A study of Mus musculus with 8 samples.

How the data were processed

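The authors sequenced RNA with TruSeq libraries, per the labels' protocols, and their reads were handled with CASAVA 1.8.2, TopHat, TopHat2 2.0.8 and Cufflinks against mouse build mm9, per the submitters' processing notes. The FPKM of each RefSeq transcript was deposited by the authors in 1 table per library, with bounds, length and a status for each estimate, per the file headers. The same tables gave a coverage value for each transcript, computed by the authors before they were deposited, per the file headers. Versions of TopHat and Cufflinks, and settings of any tool, are not given in the sources used here. Coverage was used here only to estimate depth, as coverage times length summed over transcripts. Raw reads were not used here, and no library from a control antibody was used here.

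Of 30769 transcript records, 30227 (98.2%) were matched by accession to a symbol in a gene table of assembly GRCm38.p6, used for names and neighbours alone. FPKM was summed over transcripts into 23560 genes, 536 of them without a symbol. Each library was scaled by its median ratio to the geometric mean library (factors 0.532 to 1.45), 1 FPKM was added and log2 taken. The 11832 genes with a mean of 1 FPKM or more were kept, 152 of them without a symbol, and 4286 genes had more than 1 transcript record. Estimates with a failed status were kept at the value given, which concerned Nolc1 in 4 libraries, Sulf2 and Myo3a in 3, Cnot1, Zfp568 and 4930513N10Rik in 2, and Gas2l3, Otud4 and Sp2 in 1, among others.

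RIP was set against input with limma (lmFit, eBayes with trend), with the 4 combinations of genotype and treatment as a block and 3 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values and 0.05 is the threshold. Fixed gene lists with 5 or more tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 14 lists. Simulated data had 200 genes among 11832 raised or lowered by 1 or 2. The RIP comparison returned 78% of those changed by 1 and 99% of those changed by 2, with 9 false calls among 186. With nothing changed there were 0 calls. The simulated noise was independent between genes and few genes were changed, while the real comparison called most genes. The simulation therefore does not check the scaling or the rate of false calls on the real data.

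The Adriamycin, genotype and enrichment contrasts of the report had 1 library, or 1 pair, a side. They are given as differences without p-values, with counts of genes at 1 or more in either direction. For a list, the median is given with its percentile among 10000 random lists of the same size drawn from 10 expression bins, and inside the central range means between percentiles 2.5 and 97.5. In simulation 6 of 100 lists of genes drawn at random lay outside that range. Members of a fixed list may move together, unlike genes drawn at random, so the simulation does not check the range for fixed lists. A percentile describes a list and is no measure of chance. A limma test of the RIP/input ratio between genotypes, with 2 pairs a side and 2 residual degrees of freedom, was added after the data were seen and is given in the closing section. On the real data 38 of 56 medians of the fixed lists lay outside the central range, over 14 lists in 4 contrasts.

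The lists, with fixed and tested sizes, were p53 targets (40, 39), pluripotency (32, 32), lineage (28, 16), Wnt (32, 15), G2/M (28, 28), DNA replication (28, 28), immediate early and stress (26, 24), replication-dependent histones (41, 32), ribosomal proteins (62, 62), respiratory chain (48, 48), long noncoding RNAs (32, 18), hnRNPs (29, 29), SR proteins and splicing regulators (28, 28) and fibroblast markers (23, 18). A list of short structured RNAs had 4 tested members of 17 (Rmrp, Rpph1, Rn4.5s and Scarna13), under the minimum of 5, and was not tested as a list.

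Lists, tests, thresholds and the alternatives were chosen before the data were examined, except where the text says otherwise. For 2 patterns of the closing section, tests of scaling fixed beforehand used FPKM as deposited (fibroblast median 2.51 between genotypes, respiratory chain median -2.59 in RIP against input). The scaling factors alone fixed their outcome, so they were replaced after the data were seen by a comparison with random lists. That comparison places a list against genes of similar level and cannot check the scaling itself. Genes were named by a rule fixed at the same time: the largest changes in each direction among genes past the threshold and moving the same way in all 4 combinations, or by 1 or more in both input and RIP. Short noncoding RNAs were left out of the ranks, and for RIP enrichment 5 FPKM or more was asked of both inputs of the genotype. The number was 10 a side for RIP and for Adriamycin in p53+/+, 5 for Adriamycin in p53-/- and for RIP enrichment, and 8 for the other contrasts, and some results were left out because they are withheld for evaluation. Trp53, Apela, Hnrnpl, Mdm2 and Cdkn1a were always to be named, and since no record carried the symbol Apela, NR_040692 was given in its place, a choice made after the data were seen. Members of gene families, Fam83d, Kifc1, Aurka and other members named for a count of 5 or fewer fall outside this rule. For lists, up to 4 members with the largest changes were considered. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.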

Results

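RNA was sequenced from mouse embryonic stem cells, pluripotent cells derived from the early embryo, of a mixed C57BL/6 and 129Sv background. Cultures labelled p53+/+ or p53-/- (wild type, or with both copies of the tumour suppressor gene Trp53 targeted) were left untreated or given 0.5 uM Adriamycin for 8 hours. Adriamycin (doxorubicin) is a topoisomerase inhibitor that breaks DNA. From each culture there was an input library of polyadenylated RNA and a library of RNA recovered by immunoprecipitation (RIP) with an antibody to hnRNP L, an RNA-binding protein of the nucleus. The 8 groups held 1 library each. Nothing in the labels said whether the 4 combinations of genotype and treatment were grown as separate experiments. Input libraries held between 5.67 and 7.48 Gb of bases on annotated transcripts, and RIP libraries between 3.21 and 4.94 Gb. The share of mapped material on annotated transcripts was estimated here from FPKM times length, summed over transcripts. This holds only if FPKM was computed over all mapped reads and full lengths, which the sources used here do not give. By this estimate the share was 87.6% to 90.6% in the inputs. In RIP that share was 48.9% (p53+/+, untreated), 41.1% (p53+/+, Adriamycin), 65.2% (p53-/-, untreated) and 64.2% (p53-/-, Adriamycin). Read counts per gene were not given, and the bounds given for each estimate were not used here. Gene positions are those of mouse build mm9. Changes are differences of log2(scaled FPKM + 1), which understate the change of genes near 1 FPKM. RIP against input had 4 libraries a side, and the other comparisons of this section had 1 a side and no replicate check.

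Trp53, the targeted gene (chromosome 11, 69393861 to 69405375), gave RNA in all 8 libraries. Its level in the input libraries was 236 FPKM in untreated and 173 FPKM in Adriamycin-treated p53+/+ cells, and 140 and 121 FPKM in the cells labelled p53-/-. In RIP it stood at 57.4 and 32.1 FPKM in p53+/+ and at 122 and 124 FPKM in the libraries labelled p53-/-. After scaling, the untreated p53-/- input held 59.0% of the p53+/+ level, summed over transcript records. The records differed in untreated input as deposited. That of 1868 bases stood at 43.4 FPKM in p53+/+ and 41.3 FPKM in p53-/-, and that of 1772 bases at 193 and 99.0 FPKM. The values cover whole transcripts and do not show which exons the reads came from, so they neither check nor contradict the genotype label.

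Mdm2, which encodes the ubiquitin ligase that degrades p53 (chromosome 10, 117125961 to 117147772), stood at 25.4 FPKM in untreated and 221 FPKM in Adriamycin-treated p53+/+ input. In input labelled p53-/- it stood at 14.8 and 16.5 FPKM. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29227931 to 29237667), went from 24.1 to 104 FPKM in p53+/+ input and from 21.5 to 29.4 FPKM in p53-/- input. The noncoding record NR_040692 (chromosome 8, 67552316 to 67561235) moved the other way, from 34.0 to 5.14 FPKM in p53+/+ input against 46.7 and 50.2 FPKM in p53-/- input. Its span of 8920 bases and its gap of 9729 bases to Trim61 equal those of Apela, a gene encoding a small secreted peptide, in the gene table. No accession tied the record to that symbol, so it is given here by its record name. Hnrnpl itself, whose protein the antibody binds (chromosome 7, 29595909 to 29607285), lay at 260 and 190 FPKM in p53+/+ input and at 173 and 168 FPKM in p53-/- input.

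**Figure D1:**
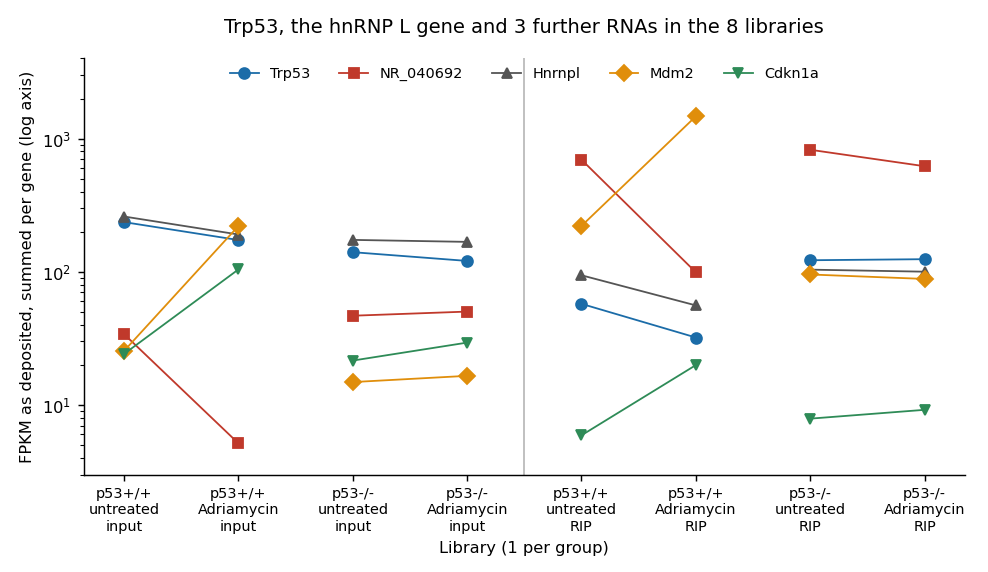
FPKM as deposited (log axis) of Trp53, NR_040692, Hnrnpl, Mdm2 and Cdkn1a in the 8 libraries, 1 point per library, with lines joining untreated and Adriamycin within a genotype and library type. Mdm2 goes from 25.4 to 221 FPKM in p53+/+ input and from 14.8 to 16.5 FPKM in p53-/- input, while NR_040692 reaches 824 FPKM in untreated p53-/- RIP.

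The first comparison asked which transcripts differed after Adriamycin in p53+/+ cells. On the higher side in input, Sbsn, which encodes the keratinocyte protein suprabasin, was higher by 4.45 (2.05 against 79.0 FPKM), Them5, a mitochondrial thioesterase gene, by 4.36, and Sytl1, of vesicle trafficking, by 4.04. The borate transporter gene Slc4a11 was higher by 3.87, the antigen-peptide transporter gene Tap1 by 3.81 and the death receptor gene Fas by 3.73. On the lower side stood Emp1 (-2.97), the growth factor genes Fgf17 (-2.86) and Bmp4 (-2.24), the pluripotency-associated genes Nr0b1 (-2.64), Lin28a (-2.44) and Eras (-2.23), and NR_040692 (-2.55).

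In all, 997 of 11832 genes were higher by 1 or more and 469 lower by 1 or more. The RIP libraries of the same cultures gave a second reading, in which 824 of the 997 and 317 of the 469 again passed 1 in the same direction. The other genes on the higher side were 1700007K13Rik (4.14), Ppp1r36 (3.96), the cytochrome P450 gene Cyp4f39 (3.84) and Tmem40 (4.88). Tmem40 overlaps the transcript NM_001168259, so its value is uncertain. On the lower side the list was completed by Bcl3 (-2.25), the amino acid transporter gene Slc7a3 (-2.14) and Zfp428 (-2.07). Counts depend on the pseudocount, and with 5 FPKM added they came to 415 higher and 203 lower.

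Known p53 target genes made up the clearest group in p53+/+ input. Of 39 measured, 24 were higher by 1 or more and 0 lower, with a median change of 1.45 (percentile 100 of 10000 random lists matched on expression). Fas (3.73), Plk2 (3.42), Perp (2.99) and Mdm2 (2.92) stood highest. Pluripotency genes lay on the other side, 17 of 32 lower by 1 or more and 1, the Nodal antagonist gene Lefty1, higher by 1.83. Their median was -1.04 (percentile 0), led by Nr0b1, Lin28a, Eras and Prdm14 (-2.04). The change of each list in these libraries is described by its median, without a p-value.

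G2/M genes of p53+/+ input had a median of -0.76 (percentile 0), with 5 of 28 lower by 1 or more, among them the mitotic kinase genes Plk1 (-1.91) and Aurka (-1.24), with Kif23 (-1.27) and Nusap1 (-1.21). The hnRNP list had a median of -0.59 (percentile 0.130) with 5 of 29 lower by 1 or more, among them Hnrnpd (-1.35), Syncrip (-1.32) and Hnrnpr (-1.28). The SR protein and splicing list had a median of -0.67 (percentile 0.0700) with 4 of 28 lower by 1 or more, among them Srsf3 (-1.78) and Srsf7 (-1.44). In RIP the hnRNP median was -0.48 (percentile 13.7), inside the central range, and the SR median -0.13 (percentile 99.8), above it. Long noncoding RNAs had a median of -0.54 (percentile 0.740, and 4.02 in RIP) with 3 of 18 lower by 1 or more, the snoRNA host genes Snhg4 (-1.88), Snhg5 (-1.20) and Snhg3 (-1.14). Among lineage genes (16 measured, median -0.35, percentile 0.0900), the mesoderm regulator gene Mesp1 was higher by 1.93, while Gbx2 (-1.88) and Otx2 (-1.38) were lower.

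The Wnt list, which holds Lef1 and Axin2 besides ligands and receptors, went both ways in p53+/+ input. Of 15 measured, 4 were higher by 1 or more, with Wnt9a at 2.44, Wnt8b at 1.83 and Wnt4 at 1.60, and 1, Lef1, was lower (-1.55). The median of 0.25 lay at percentile 82.4, inside the central range of random lists. Immediate early and stress genes were split too. Of 24, 7 were higher, among them Fos (2.10) and the mTOR inhibitor gene Ddit4 (1.92), and 4 were lower, among them Ier3 (-1.65) and Gadd45b (-1.29). Their median of 0.35 (percentile 99.9, and 88.2 in RIP) turned to -0.11 when genes under a mean of 5 FPKM were left out. DNA replication genes (median -0.27, percentile 42.3) and histone genes (0.03, percentile 28.3) lay among random lists, though in RIP the histone median was -0.38 (percentile 0.01). Fibroblast markers (0.01, percentile 51.3) did so as well.

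Ribosomal protein genes (62, median -0.06) and respiratory chain genes (48, median -0.15) had 0 members past 1 in either direction in p53+/+ input. Both medians lay above almost all random lists of equally abundant genes (percentiles 100 and 99.6), whose medians lay mostly between -0.49 and -0.20. Their own sign followed the scaling: with quantile normalization they came to 0.07 and 0.18, and with FPKM as deposited the ribosomal median was 0.07.

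The same treatment of cells labelled p53-/- left few differences in input. Only 17 genes were higher by 1 or more and 22 lower, and 11 of the 17 and 10 of the 22 were short noncoding RNAs, a class with 51 members tested. The named decreases, also seen in RIP, were Plk1 (-1.39, chromosome 7, 129302951 to 129313389), the histone gene H2aw (-1.30), D7Ertd143e (-1.21), the snoRNA host gene Snhg4 (-1.15) and Hyls1 (-1.04), a gene of centrioles. No gene other than short RNAs was higher by 1 or more in both input and RIP. Across genes, changes in p53-/- input and RIP were weakly related (Pearson r = 0.15, Spearman rho = 0.30), against r = 0.83 and rho = 0.88 in p53+/+. Without short RNAs, a step chosen after the data were seen, r was 0.33 in p53-/- and 0.88 in p53+/+. Genes are not independent replicates, so these coefficients carry no p-value.

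Mitotic genes had the lowest median of the lists in the p53-/- input. Among the 28 G2/M genes 0 lay above 0, the median was -0.55 (percentile 0), and Plk1, Hmmr (-1.12) and Aurka (-1.03) passed -1. Pluripotency genes had a median of -0.36 (percentile 0), with Zfp42 (-1.04) past the bound, followed by Nanog (-0.76). All 18 long noncoding RNAs lay below 0 as well (median -0.26, percentile 0). Of the 39 p53 targets, 0 differed by 1 or more in either direction, the median was 0.08 (percentile 99.3), and Btg2 stood highest at 0.65. In RIP the p53 target median was -0.05 (percentile 34.4), inside the central range.

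The remaining lists of p53-/- input had medians within 0.25 of 0, and 0 of their members passed 1. Histone genes stood at -0.21 (percentile 0), SR protein genes at -0.18 (percentile 0.0300), hnRNP genes at -0.17 (percentile 0.02) and ribosomal protein genes at -0.11 (percentile 1.95). In RIP the SR median was 0.25 (percentile 100), the hnRNP median -0.00 (percentile 94.6), the long noncoding median -0.18 (percentile 17.8) and the ribosomal median -0.25 (percentile 11.8). Respiratory chain genes (0.03, percentile 100) and DNA replication genes (0.03, percentile 98.3) lay above most random lists, but in RIP the respiratory chain median was -0.28 (percentile 4.07). Lineage genes (-0.03), Wnt genes (0.00), stress genes (0.03) and fibroblast markers (0.03) lay among them.

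The dependence of the response on genotype was taken as the p53+/+ change minus the change in cells labelled p53-/-, in input. It reached 5.10 for Tmem40, 4.28 for Sbsn, 4.18 for Them5, 3.88 for Sytl1, 3.77 for Slc4a11, 3.77 for the carboxypeptidase gene Cpz, 3.76 for Ppp1r36 and 3.70 for Tap1. On the negative side were Emp1 (-2.86), Fgf17 (-2.65), NR_040692 (-2.58), Lin28a (-2.15), the matrix protein gene Tgfbi (-2.10), the Ras-related gene Mras (-2.09) and Cdc42ep5 (-2.09). Amd1 (-4.53) also met the rule, but it shares its locus with Amd2 and its value is uncertain. The difference was 1 or more for 951 genes and -1 or less for 334. Of the 997 genes higher in p53+/+, 971 differed by less than 0.5 in p53-/- input and 3 were higher by 1 or more there. With 1 library per corner of the design the difference was not tested.

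**Figure D2:**
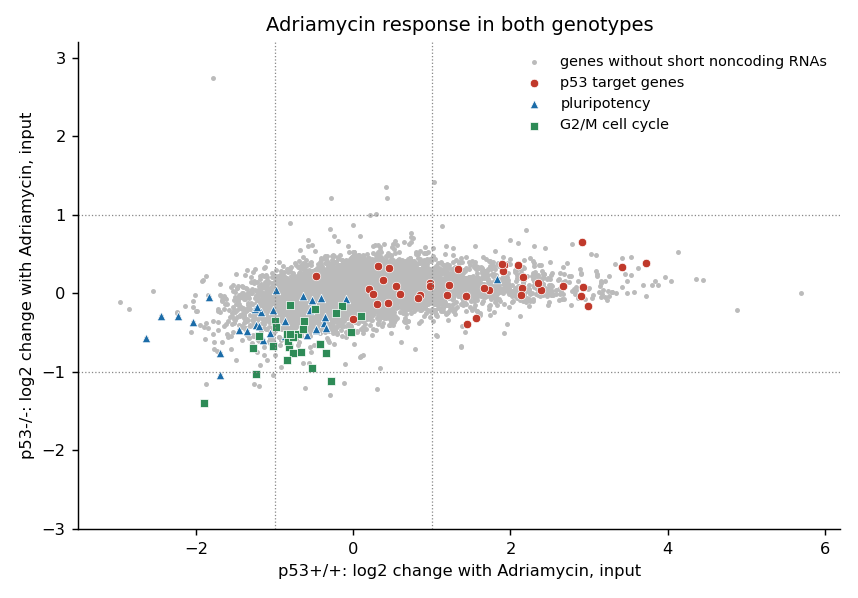
Change with Adriamycin in input (log2 of scaled FPKM + 1) in p53+/+ cells on the x axis and in cells labelled p53-/- on the y axis, 1 grey point per gene without short noncoding RNAs, with p53 targets, pluripotency genes and G2/M genes coloured and dotted lines at 1 and -1. The 39 p53 targets have a median of 1.45 on the x axis and 0.08 on the y axis, and the 28 G2/M genes medians of -0.76 and -0.55.

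By list, p53 targets had the largest dependence, with 24 of 39 at 1 or more, 0 at -1 or less and a median of 1.52 (percentile 100). Fas (3.35), Perp (3.15), Plk2 (3.09) and the phosphatase gene Ptp4a3 (2.93) led them. Pluripotency genes had a median of -0.63 (percentile 0) with 8 of 32 at -1 or less, hnRNP genes -0.54 (percentile 0.0700), SR protein genes -0.48 (percentile 0.600; in RIP the hnRNP and SR percentiles were 8.38 and 10.9) and lineage genes -0.38 (percentile 0.0900). G2/M genes, lower in both genotypes, had a median dependence of -0.20 (percentile 56.6), and 0 of 28 reached 1 in either direction. Stress genes stood at 0.28 (percentile 99.8, and 97.1 in RIP), with Ddit4 at 2.42 and Gadd45b at -1.34, and turned to -0.07 without genes under a mean of 5 FPKM. Ribosomal protein genes (0.06, percentile 100) and respiratory chain genes (-0.13, percentile 98.6) lay above random lists, the second turning to 0.15 with quantile normalization. The other medians, of Wnt (-0.02, with a mean of 0.34), DNA replication (-0.26), histone (0.20), long noncoding (-0.12) and fibroblast (-0.03) lists, lay inside the central range.

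Untreated cells of the 2 genotypes were compared next. In the input library labelled p53-/- the matrix protein genes Mgp (6.28, from 0.128 to 112 FPKM), Bgn (5.61), Col1a1 (5.30), Col1a2 (4.91), Thbs1 (4.77) and Fbln2 (4.44) were higher, as was S100a4 (5.29). Lower there were Srgn (-3.63), a proteoglycan gene, Spink1 (-3.01), Psrc1 (-2.74), Lgals2 (-2.74), the lysosomal gene Laptm5 (-2.52), 1700007K13Rik (-2.48), the endocytic adaptor gene Dab2 (-2.46) and Cox6b2 (-2.30). In total 381 genes were higher by 1 or more and 289 lower. In the Adriamycin-treated inputs 265 of the 381 and 186 of the 289 differed by 1 or more in the same direction.

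All 23 fixed fibroblast markers were higher in input labelled p53-/- at both treatments, and 12 of the 18 tested were higher by 1 or more in untreated cells. Their median was 2.20 (percentile 100) untreated and 2.21 after Adriamycin. Of the 18, 9 were also present at 1 FPKM or more in untreated p53+/+ input, with Sparc at 189, Vim at 120 and Fn1 at 50.1 FPKM. Others were near absent there, such as Lox, which was listed at 0 against 11 FPKM, and Col1a1 (0.247 against 61 FPKM). The culture protocol names no feeder cells. Every other list in this contrast is to be read beside this difference in fibroblast markers.

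**Figure D3:**
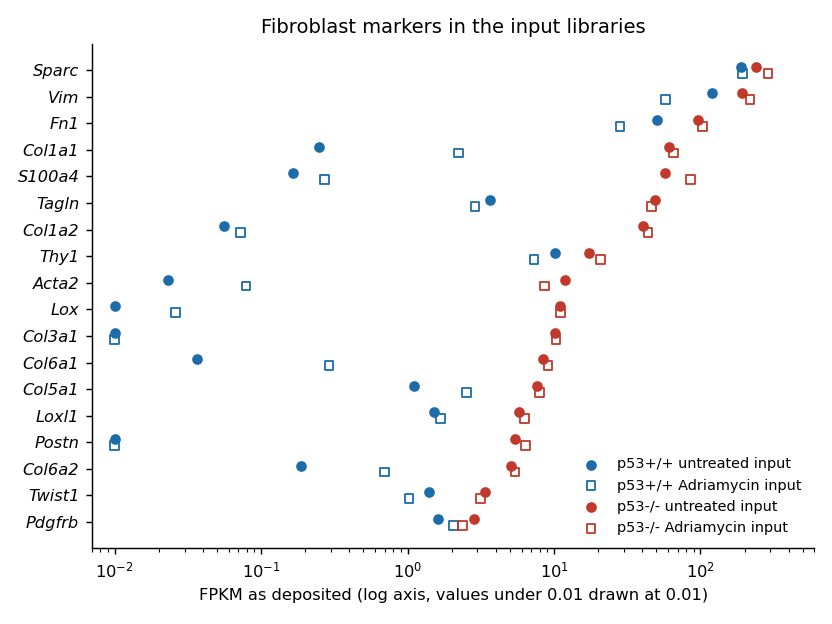
FPKM as deposited (log axis, values under 0.01 drawn at 0.01) of the 18 tested fibroblast markers in the 4 input libraries, 1 point per library, coloured by genotype, with filled circles for untreated and open squares for Adriamycin. The points of both p53-/- libraries lie to the right of both p53+/+ points for each of the 18 markers, as for Col1a1 at 61 and 65.6 against 0.247 and 2.23 FPKM.

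Genes that p53 is known to activate were lower in untreated input labelled p53-/-. Of 39, 12 were lower by 1 or more, 0 higher, and the median was -0.65 (percentile 0), with Phlda3 (-2.22), Trp53inp1 (-2.17), Bbc3 (-2.01), which encodes the apoptosis protein PUMA, and Eda2r (-1.99) lowest. After Adriamycin the median was -2.26 with 30 of 39 lower. Pluripotency genes had a median of -0.40 (percentile 0) but their largest member difference was upward: Dppa3, a maternal-effect gene, was higher by 4.38, from 6.92 to 172 FPKM, and Lefty2 by 2.46, while Tfcp2l1 (-1.75) and Tbx3 (-1.31) were lower. Lineage genes went both ways, with the keratin genes Krt18 (2.12) and Krt8 (2.11) and the intermediate filament gene Nes (1.82) higher, and the primitive endoderm genes Dab2 (-2.46) and Gata4 (-2.04) lower. Their median of -0.23 (percentile 1.99, and 2.75 in RIP) turned to 0.20 without genes under a mean of 5 FPKM. The fibroblast markers stood 2.20 higher in the same pair of libraries.

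Stress genes had a median of 0.57 (percentile 100) in untreated input labelled p53-/-, with 3 of 24 higher by 1 or more, Ier3 (2.06), Hmox1 (1.76) and Sqstm1 (1.03), and 1 lower, Myc (-1.25). Histone genes had a median of 0.47 (percentile 100), with 31 of 32 above 0 and 3 higher by 1 or more, although near-identical copies leave single members uncertain. Long noncoding RNAs had a median of 0.25 (percentile 99.5), with Neat1 (1.18) and Malat1 (1.11) higher. Below random lists lay the medians of G2/M (-0.27, percentile 0.0800), DNA replication (-0.23, percentile 0.480) and hnRNP genes (-0.22, percentile 0.430, and 46.2 in RIP). SR protein (0.13, percentile 97.4), Wnt (0.14), ribosomal protein (-0.08) and respiratory chain (-0.09) lists lay inside the central range, the last at -0.25 (percentile 0.460) in RIP. The 2.20 difference in fibroblast markers stands beside each of these lists.

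RNA recovered with hnRNP L was set against input across the 4 combinations, and this comparison was tested. The most enriched named genes were Trp53i11, a p53-inducible gene (log2 change 6.46 ± 0.16 SE, adjusted p = 6.18e-06 in limma, higher in 4 of 4 combinations), the protocadherin gene Pcdhgc3 (6.04), Fbxw5 (5.68), the endosomal GTPase gene Rab7 (5.60) and Ccdc3 (5.52). They were followed by the transcription factor gene Creb3l1 (5.47), Rpl29 (5.33), Zfand2a (5.31), the recombination repair gene Xrcc3 (5.19) and Iglon5 (5.19). Rab7 (chromosome 6, 87950429 to 87963684), for example, rose from between 71.1 and 74.4 FPKM in the inputs to between 1662 and 2040 FPKM in RIP. NR_040692 rose by 4.91 ± 0.22 SE (adjusted p = 1.35e-05 in limma), from 34.0 to 694 FPKM in untreated p53+/+ cells.

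Depleted from RIP were messages of ribosomes and mitochondria among others: Rps15a (-3.11 ± 0.12 SE, adjusted p = 1.1e-05 in limma, lower in 4 of 4), the ATP synthase gene Atp5e (-2.91), the proton pump gene Atp6v0c (-2.90), Rpl39 (-2.88), Ndufb6 (-2.85), Rps13 (-2.79), the thioredoxin gene Txn1 (-2.75), Rps21 (-2.74), Rps29 (-2.71) and NM_010760 (-2.69). Mdm2 rose by 3.60 ± 0.25 SE (limma adjusted p = 3.09e-05) and Cdkn1a fell by 0.90 ± 0.08 SE (adjusted p = 9.4e-05). Hnrnpl fell by 0.24 (adjusted p = 0.0343), a call lost in 6 of the alternatives. Trp53 did not pass (-0.22 ± 0.29 SE, adjusted p = 0.51, limma), with ratios of -0.87 and -0.98 in p53+/+ and 0.36 and 0.61 in libraries labelled p53-/-.

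By limma, 4412 of 11832 genes were higher in RIP and 4470 lower at an adjusted p under 0.05, and 1914 and 1588 of them by 1 or more. The direction was the same in all 4 combinations for 8767 of the 8882 calls. The split is relative to the scaling, which sets the typical gene near 0. With FPKM as deposited, where the median gene shifted by -0.72, 1540 genes were higher and 7246 lower, and 17.5% of calls were upward instead of 49.7%. No library from a control antibody was used here, so enrichment is over input alone, and p-values measure the spread between the 4 combinations.

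Messages of the nuclear-encoded respiratory chain were depleted almost without exception. Of 48, 47 fell and 0 rose, with a median of -1.67 (camera adjusted p = 7.69e-13), as for Atp5e, Ndufb6, Cox7a2 (-2.64) and Ndufa1 (-2.62). Ribosomal protein messages fell in 44 of 62 and rose in 11 (median -1.38, camera adjusted p = 4.65e-05), with Rps13, Rps21, Rps29 and Rps16 (-2.63) lowest. Messages for hnRNPs fell in 20 of 29 and rose in 4 (median -0.69, camera adjusted p = 0.00182), led by Hnrnpf (-2.27) and Hnrnpab (-1.75), and those of DNA replication fell in 20 of 28 and rose in 5 (median -0.71, camera adjusted p = 0.0244), with Pcna (-1.53) lower and Gins2 (2.52) higher. SR protein and splicing messages rose in 17 of 28 and fell in 5 (median 0.82, camera adjusted p = 0.0322), led by Luc7l3 (1.81), Rbm25 (1.68), Srrm1 (1.62) and Son (1.51). None of these 5 calls held with an estimated correlation, where the adjusted p was 0.833 for the SR list and 0.767 for each of the other lists.

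**Figure D4:**
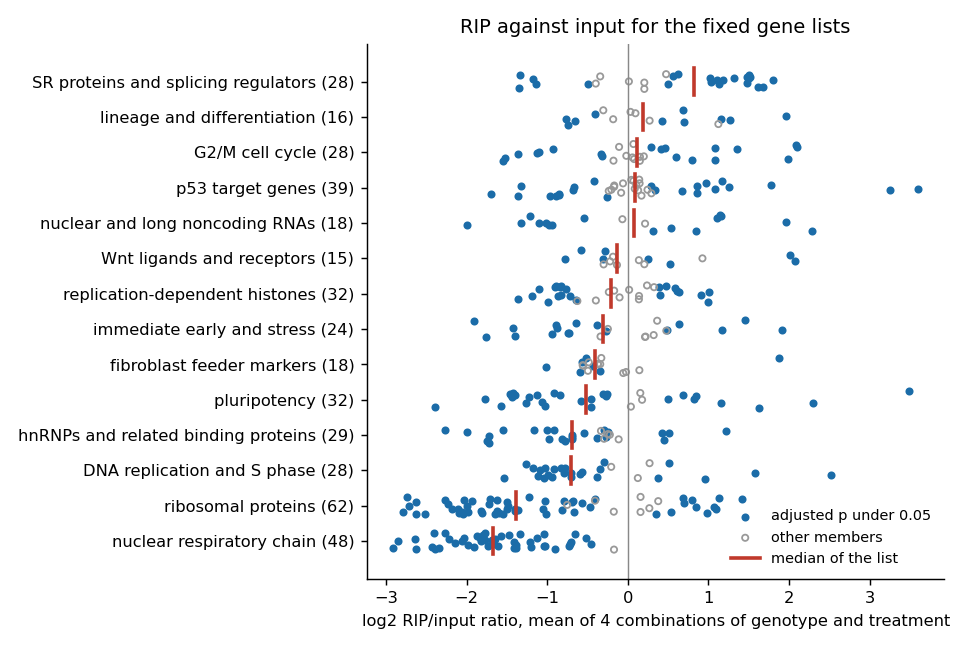
Log2 RIP against input of the members of each fixed list (x axis), 1 point per gene as the mean of 4 combinations, filled where the adjusted p was under 0.05 in limma, with the list median as a line. The 48 respiratory chain genes have a median of -1.67 and the 28 SR protein and splicing genes a median of 0.82.

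Quantile normalization ended the calls of the ribosomal and DNA replication lists (adjusted p = 0.0728 each), with medians of -0.73 and -0.64. The DNA replication call also ended with a mean of 5 FPKM or more (0.055, median -0.74). The SR call ended without the p53+/+ Adriamycin pair (adjusted p = 0.0612, median 0.65), without the p53-/- Adriamycin pair (0.068, median 0.75), with a pseudocount of 0.1 (0.0518, median 0.84) and with FPKM as deposited, where its median was -0.09. Adjusted over the list alone, the counts of members that rose and fell were the same in these 5 lists. Transcript length differed between the lists, with medians of 665 bases for respiratory chain genes and 2661 bases for all genes. With the length trend removed, a step chosen after the data were seen, the ribosomal list (adjusted p = 0.087, median -0.55) and the SR list (0.0688, median 0.52) no longer passed.

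Of the 9 lists that did not pass, the pluripotency and fibroblast lists passed without a filter on low values (camera adjusted p = 0.0127 each). Pluripotency messages had 21 of 32 lower and 8 higher (median -0.52, camera adjusted p = 0.0978), with Klf4 at 3.49, the Polycomb cofactor gene Jarid2 at 2.30, Dppa5a at -2.39 and Nanog at -1.77. Messages of p53 targets were divided, 12 higher, 11 lower and 16 not passing of 39 (median 0.09, adjusted p = 0.83), or 11 and 11 adjusted over the list alone. Mdm2 and the sulfatase gene Sulf2 (3.25) were enriched and Pmaip1 (-1.70) depleted. The Sulf2 value is uncertain, since its estimate failed in 3 libraries. Stress genes had 5 of 24 higher and 12 lower (median -0.31, adjusted p = 0.442), with Egr1 at 1.91 and Hmox1 at -1.91. G2/M genes had 11 of 28 higher and 8 lower (0.11, adjusted p = 0.648), with Cenpe at 2.10 and Ube2c at -1.54.

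Long noncoding RNAs had 8 of 18 higher and 8 lower (median 0.07, adjusted p = 0.873), with Meg3 at 2.29, Firre at 1.96 and Snhg3 at -1.99. Lineage genes had 6 of 16 higher and 4 lower (0.18, adjusted p = 0.773), and histone genes 9 of 32 higher and 13 lower (-0.20, adjusted p = 0.512). With the length trend removed, the histone list turned and passed (median 0.35, camera adjusted p = 0.00363). Among Wnt genes 4 of 15 were higher and 4 lower, or 2 and 3 adjusted over the list alone. Their median was -0.13 and their mean 0.22, and the camera direction was down (adjusted p = 0.873). Fzd7 (2.07) and Wnt4 (2.02) stood highest. Fibroblast markers had 1 of 18 higher, Fn1 (1.88), and 6 lower, or 5 adjusted over the list alone (median -0.40, adjusted p = 0.14). Counts for the pluripotency, stress, G2/M, long noncoding, lineage and histone lists were the same adjusted over the list alone.

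Whether Adriamycin moved RNA into or out of the hnRNP L fraction was read from the change in the RIP/input ratio. In p53+/+ cells 145 genes gained by 1 or more and 86 lost, against 35 and 41 in cells labelled p53-/-. With FPKM as deposited the p53+/+ counts were 64 and 215, so their balance turned with the scaling. Named gains in p53+/+ were Amd2 (3.40), Gm12669 (2.45), the kinase gene Tlk2 (2.23), Rps27 (2.04) and Cbs (1.98), which encodes cystathionine beta-synthase. Named losses were the RNA polymerase II subunit gene Polr2d (-1.77), Platr5 (-1.33), NM_001168259 (-1.26), Pih1d1 (-1.16) and Epp13 (-1.16). In p53-/- they were Rps27 (1.93), NM_009089 (1.37), Gm12669 (1.14), the telomere gene Ctc1 (1.13) and Cnot2 (1.06) above, and Akr1b3 (-1.81), NR_046233 (-1.59), the mitochondrial tRNA ligase gene Lars2 (-1.28), NR_024327 (-1.10) and Vkorc1 (-1.06) below. Amd2 shares its locus with Amd1, Cnot2 with NR_024327 and NM_001168259 with Tmem40, and Rps27 has near-identical copies, so these are uncertain. Each ratio rests on 1 RIP and 1 input library and was not tested.

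SR protein and splicing messages had medians of 0.46 in p53+/+ and 0.37 in p53-/- in this ratio (percentile 100 in each), with 25 and 26 of 28 above 0 and 1 and 0 at 1 or more. Messages for hnRNPs stood at 0.22 (percentile 100) and 0.11 (percentile 98.6), the first at -0.04 with FPKM as deposited. Respiratory chain messages lay at -0.26 and -0.27 (percentiles 0.0300 and 0.140), and histone messages at -0.30 (percentile 0) and -0.16 (percentile 0.790). Ribosomal protein messages lay at -0.30 (percentile 0) in p53+/+ and -0.14 (percentile 34.0) in p53-/-. DNA replication messages stood at 0.16 (percentile 100) and 0.05 (percentile 92.2), and G2/M messages at -0.01 (percentile 90.1) and 0.19 (percentile 100). For p53 targets the medians were -0.05 and -0.17 (percentiles 30.1 and 1.04), and for pluripotency genes 0.02 and -0.15 (percentiles 98.1 and 13.5), the first changing sign in 4 alternatives. Lineage (-0.12 and -0.09), Wnt (0.00 and -0.06), stress (0.00 and -0.02) and fibroblast (-0.02 and -0.10) lists lay inside the central range of random lists, the lineage mean in p53+/+ being 0.15. Long noncoding RNAs lay at -0.04 (percentile 68.4) and 0.13 (percentile 97.6). NR_040692 stood at -0.10 in p53+/+ and -0.51 in p53-/-, and Mdm2 by -0.05 and -0.26.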

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

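Of the tests of this part, those of the fibroblast count, p53 loss, scaling against random lists, transcript length, histone messages, p53+/+ cells in the other culture, the disrupted gene and the RIP/input ratio by genotype were chosen after the data were seen.

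Fam83d, a spindle gene, had an Adriamycin change of 1.37 in p53+/+ input and -0.67 in input labelled p53-/-, a difference of 2.04, with 0.94 and -0.70 in RIP. The motor gene Kifc1 had 0.78 and -0.71, a difference of 1.49, with 0.79 and -0.61 in RIP. These 2 of 11781 genes were singled out because both libraries of each genotype moved by 1.5-fold or more in opposite directions, and the difference was not tested. Trp53 was singled out by a test of the difference between genotypes in its RIP/input ratio. That ratio was 1.41 ± 0.17 SE higher in p53-/- (limma adjusted p = 0.0171, 2 residual degrees of freedom). The 2 pairs of a genotype were its untreated and its Adriamycin pair. The p-values of this test thus measure the spread between treatments, and not between cultures of a genotype. Genotype cannot be told apart here from any other difference between the cultures. The Trp53 difference was 1.64 with quantile normalization (limma adjusted p = 0.0378) and 2.13 with FPKM as deposited (0.00192). Leaving out 1 pair, which leaves an arm of 1 pair assumed to vary like the other, gave 1.46 and 1.35 without a p53+/+ pair (limma adjusted p = 0.0005 and 0.00215), and 1.53 without the p53-/- untreated and 1.28 without the p53-/- Adriamycin pair, where the call ended (0.0819 and 0.169). Mdm2 passed in the other direction (-1.18, limma adjusted p = 0.0226) and did not with FPKM as deposited (-0.42, adjusted p = 0.212), with quantile normalization (-1.05, 0.0586), or without the p53-/- untreated (-1.31, 0.0837) or Adriamycin pair (-1.05, 0.192). The RIP libraries also stood apart by genotype in the share of mapped material on transcripts as estimated from FPKM and length. It was 65.2% and 64.2% in p53-/- against 48.9% and 41.1% in p53+/+. Across all genes this limma test called 99 higher and 285 lower in p53-/-, and 4622 and 179 with FPKM as deposited. With quantile normalization it called 43 and 95. The counts were 402 and 820 without the p53+/+ untreated pair, 272 and 625 without the p53+/+ Adriamycin pair, 9 and 8 without the p53-/- untreated pair, and 2 and 2 without the p53-/- Adriamycin pair.

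All 18 tested fibroblast markers were higher in input labelled p53-/- at both treatments. Fibroblasts in those cultures could give this pattern. Scaling by a factor per library moves genes of similar level alike, so it could not set the list apart from them. The median of 2.20 (bootstrap interval 0.92 to 3.21) lay outside the -0.20 to 0.22 of random lists matched on expression. This places the list against such genes and cannot check the scaling itself. Loss of p53 in the stem cells themselves stays open, as the median of 2.21 in Adriamycin-treated libraries would follow from either. The prediction for fibroblasts was written after the markers had been seen, so the fit is weak evidence.

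Respiratory chain and ribosomal protein messages were low in RIP, and both are short (median 665 and 730 bases against 2661). With the length trend removed the respiratory median went from -1.67 (bootstrap interval -1.82 to -1.40) to -0.95 (-1.18 to -0.71). The trend removed here thus did not account for the whole difference. The interval treats list members as independent, and length and expression level were not removed together, so length is not excluded more widely. Before that step the respiratory interval lay below random lists matched on expression, which lay between -1.01 and -0.06. The ribosomal median of -1.38 lay below its random lists (-0.99 to -0.13), but its interval (-1.62 to -0.75) overlapped them. Scaling moves a list and its random lists alike, so these comparisons cannot check the scaling itself. For the ribosomal list length stays open, with a median of -0.55 (interval -0.84 to 0.05) once the length trend was removed. Capture of RNA with and without a poly(A) tail stays open, with histone messages at a median of -0.20, and no biological explanation was tested.

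Trp53 RNA in the untreated input labelled p53-/- stood at 59.0% of the p53+/+ level, in the Adriamycin input at 71.9% and in untreated RIP at 139%. If cells of the p53+/+ culture had given the untreated input level, the p53 target median after Adriamycin would be 1.10 in input labelled p53-/-. It was 0.077 (bootstrap interval -0.004 to 0.13), which excludes that mixture. Other p53+/+ cells, with another response to Adriamycin, were not tested. A disrupted gene that still gives RNA could account for the Trp53 level and stays open, because exon values are not given.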

How the results depend on the processing

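The alternatives without short noncoding RNAs, with the length trend removed and with the Adriamycin-treated libraries were chosen after the data were seen, and all others before the data were examined. Single genes and lists stayed the same in 2138 comparisons with an alternative, moved in 184, got weaker in 36 and stronger in 6, and turned in 17. Counts were taken as the same within 1.5 times, and main list medians as the same inside their bootstrap interval over genes. By these rules counts and main medians stayed the same in 138 comparisons and moved in 55. Fewer genes are tested with a mean of 5 FPKM or more, and for the other settings the cause was not tested. RIP and input were paired by genotype and treatment, as the labels carry no replicate numbers and each group held 1 library. With this block left out, genes higher in RIP went from 4412 to 2690 and lower from 4470 to 2672. Of 35 splits of the libraries into 4 and 4, 1, the real one, called as many genes. The highest other, with 292 calls, parted the libraries by genotype. Every other split leaves the difference between RIP and input in its error, so few calls there were fixed beforehand. These splits therefore say nothing about chance. Of 8 swaps within the block, 1, the real one, did so and the highest other called 0, but 8 swaps are too few for a test. Depth is known as bases on transcripts, from 3.21 to 7.48 Gb, and the bounds given for each FPKM were not used here.

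For Adriamycin in p53+/+ input, 997 higher became 415 with a pseudocount of 5 and 503 with a mean of 5 FPKM. The 469 lower became 796 with a pseudocount of 0.1 and 203 with 5. In p53-/- input, 17 higher became 36 with a pseudocount of 0.1, 11 with 5, 8 with a mean of 5 FPKM, 30 with the highest isoform alone, 2 in both input and RIP and 6 without short RNAs, and 22 lower became 10 with a pseudocount of 5, 7 in both and 12 without short RNAs. For the dependence on p53, 951 higher became 406 with a pseudocount of 5 and 489 with a mean of 5 FPKM, and 334 lower became 675 with a pseudocount of 0.1, 116 with 5 and 194 in both. Between untreated genotypes, 381 higher became 704 with a pseudocount of 0.1, 123 with 5, 200 with a mean of 5 FPKM and 919 in the Adriamycin-treated libraries. The 289 lower became 615, 73, 636 in RIP alone and 1279 in the Adriamycin-treated libraries. The fibroblast median of 2.20 became 3.84 with a pseudocount of 0.1 and 0.87 with 5.

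For RIP enrichment in p53+/+, 145 higher became 262 without a filter, 48 with a mean of 5 FPKM, 64 with FPKM as deposited and 219 with the highest isoform alone. The 86 lower became 158 with a pseudocount of 0.1, 40 with 5, 29 with a mean of 5 FPKM, 215 with FPKM as deposited and 152 with the highest isoform alone. In p53-/-, 35 higher became 62 with a pseudocount of 0.1, 20 with 5, 92 with the highest isoform alone and 15 without short RNAs, and 41 lower became 111, 20, 22 with a mean of 5 FPKM, 90 with the highest isoform alone and 27 without short RNAs. For RIP against input, 4412 higher became 2523 with a mean of 5 FPKM, 1540 with FPKM as deposited and 1914 when a change of 1 was asked for, and 4470 lower became 7246 with FPKM as deposited and 1588 at a change of 1. The 5 lists called became 0 with an estimated correlation and 3 with quantile normalization.

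Signs turned as follows. The pluripotency median of RIP enrichment in p53+/+ (0.02) became -0.00993 with a pseudocount of 0.1, -0.020 with a mean of 5 FPKM, -0.19 with FPKM as deposited and -0.031 with quantile normalization. With a mean of 5 FPKM, lineage genes between genotypes (-0.23) became 0.20, stress genes after Adriamycin in p53+/+ (0.35) became -0.11 and in the dependence (0.28) became -0.066, and histones in p53-/- RIP enrichment (-0.16) became 0.0081. With FPKM as deposited, DNA replication genes in p53+/+ RIP enrichment (0.16) became -0.087, hnRNP genes there (0.22) became -0.044, and ribosomal protein genes after Adriamycin in p53+/+ (-0.06) became 0.069, and 0.074 with quantile normalization. Respiratory chain genes became 0.18 there (from -0.15) and 0.15 in the dependence (from -0.13) with quantile normalization. In RIP against input, Trp53 (-0.22) lay between -0.49 (without the p53-/- Adriamycin pair) and 0.034 (without the p53+/+ Adriamycin pair) when 1 combination was left out and became 0.025 with the length trend removed, and histones (-0.20) became 0.35 with the length trend removed (limma camera adjusted p = 0.00363).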

Other observations

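The families of genes sharing a symbol stem described in this part were chosen after the data were seen, from 351 families with 5 or more tested members, and none was tested as a list.

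Genes of the X-linked Xlr family, known from lymphocytes and germ cells, were higher in untreated input labelled p53-/-, 10 of 10 above 0 with a median of 2.13, and 2.02 in the Adriamycin-treated inputs. All 6 tested Rhox homeobox genes, a reproductive cluster, were also higher, with medians of 1.11 and 0.77. Pramel genes (11) had medians of -0.67 and -1.23. Fibroblast markers stood 2.20 higher in the same untreated pair, and near-identical copies leave single Xlr genes uncertain.

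In RIP against input, the protocadherin genes of the Pcdhga (10) and Pcdhgb (6) groups had medians of 2.63 and 2.81, and every member passed in limma. They share their last exons, so they are not independent. The Arid family (8) stood at 1.63 with 7 passing and the Smc family (7) at 1.34 with 6 passing. Over all genes 8882 of 11832 passed, so these counts of passing members alone do not set the families apart. Proteasome subunit genes of the Psmb family (10) stood at -1.72, peroxiredoxin genes (6) at -1.84 and mitochondrial import genes of the Timm family (15) at -1.53. Mitochondrial ribosome genes stood at -0.89 (Mrpl, 49) and -0.85 (Mrps, 29). The ratio went with transcript length over all genes (Spearman rho = 0.41), from a median of -0.81 in the shortest to 0.62 in the longest decile of genes. Median lengths were 959 bases for Psmb, 1196 for Prdx, 1179 for Timm, 1029 for Mrpl and 1053 for Mrps. They were 4851 for Smc and 5739.5 for Arid, so the low families were shorter than the high ones. Among the low families the order did not follow length, since Timm and Prdx were longer than Mrpl and Mrps but lower. Genes of 1037 to 1472 bases had a median of -0.47. How far length accounts for these families was not tested. The 5 tested genes grouped by the symbol stem Acad (acyl-CoA dehydrogenase) were all above 0 after Adriamycin in p53+/+ input. Their median of 0.94 lay under the bound of 1 used for counts, and the stem alone defined the group.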
